A study of Mus musculus with 7 samples.

How the data were processed

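RNA was measured by sequencing of mouse salivary glands, the parotid gland and the submandibular gland, which are separate paired organs that secrete saliva. The 7 libraries used here fall into 3 groups taken from the sample labels: parotid at postnatal day 18 (P18, n = 2), submandibular gland at P18 (n = 2) and parotid of adult mice aged 12 weeks (n = 3). In each deposited table, 2 further columns of per-sample values matched no sample label and were not used here. Per the labels' protocols, polyadenylated RNA from 1 µg of total RNA went into an Illumina TruSeq RNA preparation. A label describes the material as whole tissue, whereas the extraction protocol speaks of isolated epithelial cells, so the cell content of the samples is open. The labels do not say whether replicates of a group came from separate animals. The p-values below therefore measure only the spread between these samples, which may be technical. Adult replicate 1 is an exception, since its sex-linked transcripts, given below, differ from those of the other adult libraries.

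The authors deposited a table of raw counts per gene symbol and a table of TPM (counts divided by gene length and scaled to a fixed total). Per the submitters' processing notes, TopHat2 2.1.1, Bowtie2 2.2.6, featureCounts 1.5.1 and DESeq2 1.20.0 were used with genome build mm9. The notes used here give no role or order for these tools, and the counting settings, including strand and multi-mapping, are not given in the sources used here. Reads from near-identical gene copies can be split or lost in such counts. Values of kallikrein 1b, Dcpp, Smr, proline-rich protein, amylase, secretoglobin, major urinary protein, ribosomal protein and globin genes are therefore uncertain between copies. Genes that overlap another gene, including antisense partners, are uncertain as well. The reference annotation at hand belongs to another build, so genes are named by the symbols of the deposited counts and no coordinates are given.

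All tests started from the deposited counts. The table held 23366 genes, of which 15129 passed edgeR's expression filter (a minimum count of 10 and a total of at least 15). Total counts per library were 12844534 and 14421876 in P18 parotid, 15339757 and 13152194 in P18 submandibular gland, and 15972076, 21982287 and 28856127 in adult parotid. Composition factors came from edgeR's TMM method and were 1.72 and 1.55 for P18 parotid, 1.10 and 1.04 for P18 submandibular gland, and 0.640, 0.715 and 0.718 for adult parotid. Normalised read counts below are CPM (edgeR's cpm function), scaled by the library size multiplied by its factor. Gene tests used edgeR 4.0.16 (quasi-likelihood F test, glmQLFit and glmQLFTest, in R 4.3.3) in a single fit of the 3 groups with 4 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 fold changes are standard errors derived from the F statistic.

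The comparisons were P18 submandibular gland minus P18 parotid, adult minus P18 parotid, and P18 submandibular gland minus adult parotid, the last only to ask which gland differences also stood against the adult libraries. A total of 25 gene lists were fixed from textbook knowledge before the data were examined. They cover secretory products, ducts, secretion machinery, growth and development, other cell types a dissected gland can hold, stress and interferon responses, ribosomal proteins and oxidative phosphorylation. Lists with at least 3 measured members were tested with camera from limma 3.58.1, which compares a list with all other genes. The preset inter-gene correlation was 0.01, the adjustment ran over the lists, and the p with an estimated correlation is given beside each call. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone.

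The rule for named genes was fixed at the same time. In each direction it takes the 8 largest changes past the threshold with a mean of at least 20 CPM in the higher group, no overlap between groups and a symbol that is not a clone or model name. From each list it takes the 2 members with the smallest adjusted p in each direction, or the most abundant member where none passed. Not all genes that the rule names are printed. Other genes named in the text were chosen after their values were seen. A fold against a group without a count is a lower bound set at 3 counts over that group. With 1 to 3 counts in a group the ratio is given with its 95% exact Poisson interval. Such bounds and intervals cover counting error only, since reads are not independent molecules.

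No replicate pair agreed within sampling noise. The chi-square per degree of freedom over genes with at least 10 counts in sum was 197 between the P18 parotid libraries, 13.3 between the P18 submandibular libraries, and 67.6, 61.7 and 46.7 between adult libraries, so no library was merged with another. The chi-square sets the spread against counting noise alone and does not show that the libraries came from separate animals. The procedure was tested on simulated counts with the means and library sizes of these samples and 200 changed genes per draw. In 5 draws of 14739 to 14850 genes tested, 2.75% of 2-fold, 56.5% of 4-fold and 92.0% of 16-fold changes were found for the gland comparison, with 7.29% false calls, above the nominal rate. For the age comparison the shares were 6.95%, 62.8% and 96.9%, with 6.74% false calls. In 1 draw of 15129 genes, DESeq2 gave 27.9% false calls for the gland comparison and 22.8% for the age comparison. Small changes were therefore mostly out of reach at this number of samples. The draws gave each gene the same spread in all groups. In the data, 3587 genes were over 2-fold apart between the P18 parotid libraries and 652 between the P18 submandibular libraries. The rates of false calls in the data may therefore differ from those simulated.

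Alternatives fixed with the rule were DESeq2 size factors, upper quartile factors and plain library sizes as scalings, removal of the 50 most abundant genes, no filter on low counts, DESeq2 1.42.0 as the tool, and limma on log2 of the authors' TPM plus 1 or plus 0.1, for genes with a TPM of at least 1 in 2 libraries or without that filter. Further alternatives were a test against a fold of 2, fits of only the groups compared, replicate number as a block, and leaving out each of the 7 libraries in turn. Chosen after seeing the data was leaving out P18 parotid replicate 2 and adult replicate 1, below called both libraries that stood apart. With 2 P18 parotid libraries, the data cannot say which of them stands apart from its group. Also chosen then were removing RNA classes without a poly(A) tail, a gene length trend as an offset, and naming the largest falls after leaving those RNA classes out. Comparisons that share libraries were set beside 50 simulated draws without group effects. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.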

Results

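The transcriptomes of mouse parotid and submandibular glands were compared at P18, and those of the parotid between P18 and adulthood at 12 weeks. There were 2 P18 parotid, 2 P18 submandibular and 3 adult parotid libraries, with 12844534 to 28856127 counts each. Values are means ± SD of normalised CPM over these libraries unless stated otherwise.

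A few secretory genes took much of the RNA, and their share differed between the groups. The 10 most abundant genes held 13.4% of counts in P18 parotid (17.8% and 9.05% in the libraries), 43.1% in P18 submandibular gland (42.1% and 44.0%) and 63.4% in adult parotid (65.4%, 62.2% and 62.6%). Bpifa2, which encodes a secreted parotid protein, led both parotid groups, with 6.89% ± 5.89 of counts at P18 and 28.8% ± 2.87 in the adult. Amy1, the salivary amylase, held 0.454% ± 0.209 at P18 and 10.9% ± 1.54 in the adult. Smgc, a mucin-like product of the immature submandibular gland, held 21.1% ± 2.31 of counts in P18 submandibular gland, and the secretoglobins Scgb1b27 and Scgb2b27 held 5.73% ± 0.0217 and 3.97% ± 0.326. These genes were picked as the most abundant. The serous list held 8.66% ± 7.40, 6.69% ± 0.701 and 56.8% ± 2.44 of counts in P18 parotid, P18 submandibular and adult parotid, and the mucous list 0.468% ± 0.225, 21.1% ± 2.31 and 1.22% ± 0.297.

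**Figure D1:**
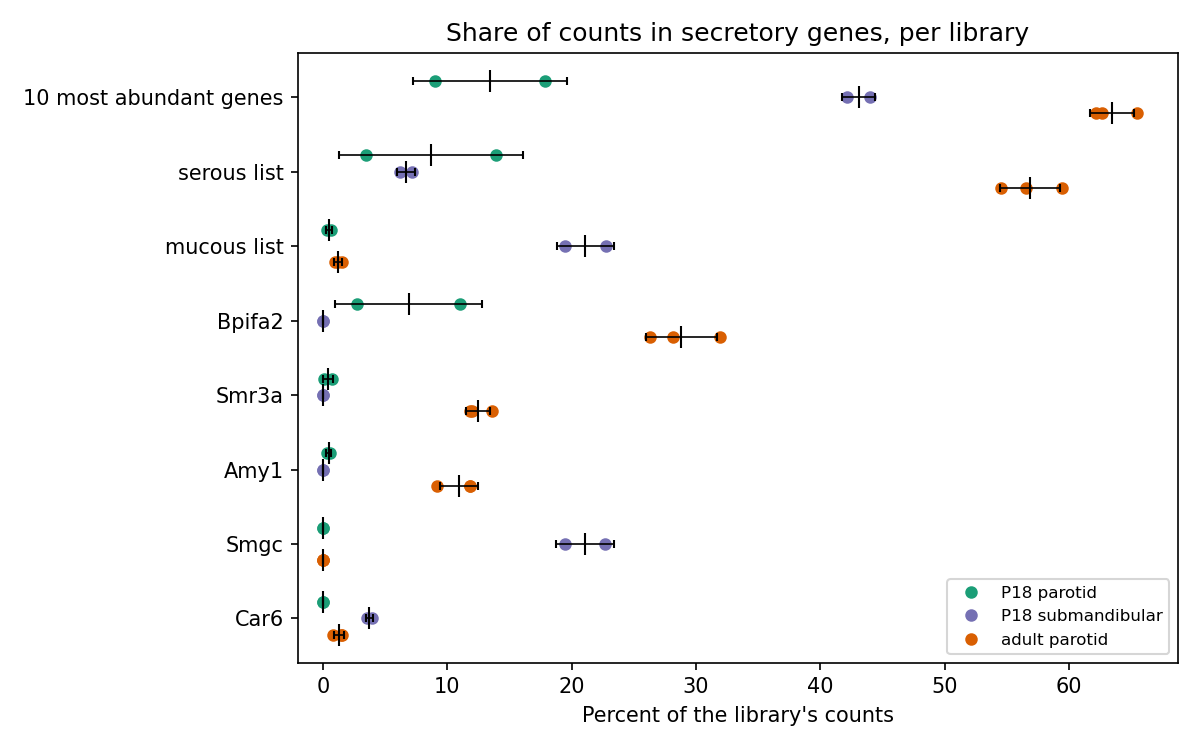
Share of each library's counts (percent, horizontal axis) held by the 10 most abundant genes, by the serous and mucous lists and by 5 single genes. Points are libraries, vertical marks group means and bars ± 1 SD (n = 2, 2 and 3). The 10 most abundant genes held 62.2% to 65.4% in adult parotid and 9.05% and 17.8% in P18 parotid.

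The title of the series names the comparison of parotid and submandibular glands, which was made here at P18. Smgc was 197670 ± 29816 CPM in submandibular gland against 4.73 ± 1.10 in parotid, a log2 difference of 15.35 ± 3.82 (SE, adjusted p = 0.0277, edgeR). The secreted carbonic anhydrase Car6 was 34947 ± 1060 against 21.0 ± 14.9 CPM (10.70 ± 1.28, adjusted p = 0.00403), and the receptor tyrosine kinase Ret 124 ± 12.7 against 4.15 ± 0.166 CPM (4.90 ± 0.20, adjusted p = 0.000299). Conversely, adipocyte genes were higher in P18 parotid, among them Ucp1, the uncoupling protein of brown fat, with 1739 ± 1506 against 0.265 ± 0.0397 CPM (-12.65 ± 1.25, adjusted p = 0.00282).

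In total 1537 genes were higher and 2149 lower in submandibular gland, 3686 of 15129 tested, and 401 and 1219 of them differed by 4-fold or more. All 3686 had no overlap between the libraries of both groups, as had 64.9% of all genes tested, where chance gives 33.3%. The other genes named by size among the increases were Scgb2b26, Prol1, the homeobox gene Tlx1, Lman1l, Tmem59l and the transcription factor gene Foxa1. Prol1 was 4916 ± 3035 against 0.837 ± 0.677 CPM, and Scgb2b26 17751 ± 523 against 1.06 ± 0.360 CPM. Tlx1, without a count in P18 parotid, was at least 325-fold higher, and with 2 parotid counts each the ratios of Lman1l and Foxa1 were 3913 (1083 to 32312) and 678 (188 to 5598), with 95% intervals in brackets. Tmem59l had a ratio of 677 (232 to 3283). Among the decreases, Otop1 was at least 490-fold, the fatty acid receptor gene Ffar4 at least 342-fold and the cardiac actin gene Actc1 at least 225-fold higher in P18 parotid. The adipocyte genes Cfd, Cidec and Adipoq had parotid to submandibular ratios of 5104 (1746 to 24748), 4925 (1364 to 40671) and 3560 (1218 to 17264). Cidea, a lipid droplet gene of brown fat, was 3140-fold lower in submandibular gland.

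These calls rested on the submandibular pair: without submandibular replicate 1 the comparison called 441 genes and without replicate 2 it called 148, the lone library being assumed to vary like the other groups. Without adult parotid replicate 2 it called 2385. Of 71 named genes past the threshold, 20 kept their calls whichever library was left out, among them Adipoq, Agr2, Car3, Car6, Cfd, Cidea, Cidec, Dcpp2, Dcpp3, Foxi1, Klk1b5, Klk1b9, Prol1, Ret, Scgb2b26, Sec23b, Tmem59l and Ucp1. Smgc lost its call without either P18 parotid or either submandibular library, and DESeq2 gave it no adjusted p. With only the 2 groups in the fit 1349 genes were called, 53 of the named ones among them, and against a fold of 2 there were 969, with 47 of the named. Leaving out P18 parotid replicate 2 and adult replicate 1 together, chosen after seeing the data, gave 6245. With plain library sizes the median of all genes moved by -0.61 and 8.71% of 5967 calls were higher in submandibular gland, against 41.7% of the calls with TMM. On log2(TPM + 1) the median moved by -0.83 and 4.97% of 9291 calls were higher. Both times Acta2, Atp5g3, Pcna, Pitx1 and Rps27l lost their calls.

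The serous and proline-rich list, products of protein-secreting acinar cells, split between the glands. Of 14 measured members 4 were higher and 6 lower in submandibular gland and 4 did not pass the test (4 and 7 adjusted over the list alone). The 4 higher members were Prol1 (also named Muc10), Car6, Pip and Smr2. The proline-rich genes Prpmp5 and Prb1 were 94.5-fold and 123-fold lower (adjusted p = 0.00564 and 0.00823). How far the list splits therefore depends on counting Prol1 in it, though Car6 and Pip were higher as well. Bpifa2 did not pass the test, with 81.1 and 263 CPM in the submandibular libraries against 64437 and 17559 in P18 parotid (-7.90 ± 2.52, adjusted p = 0.0585). The list's median was -5.28 (-4.42 with 1 member at its bound) and its mean -1.95 (adjusted p = 0.676, adjusted p = 0.896 with an estimated correlation). Without P18 parotid replicate 2 the list passed (median -5.91, adjusted p = 0.00301), as it did without both libraries that stood apart (adjusted p = 0.000916), while on log2(TPM + 1) and log2(TPM + 0.1) camera ranked it above other genes (adjusted p = 0.0364 and 0.0278). The mucous list split too, with 4 of 10 members higher and 3 lower (4 and 3 adjusted over the list alone, median 2.08, camera adjusted p = 0.277, adjusted p = 0.721 with an estimated correlation). The 3 lower members were Dcpp1, Dcpp2 and Dcpp3, with Dcpp1 at 2059 ± 938 CPM in P18 parotid and 9.36 ± 12.2 in submandibular gland. The split therefore depends on counting the Dcpp genes in this list. The disulfide isomerase gene Agr2 was 418-fold and the mucin-type glycosyltransferase gene Gcnt3 44.3-fold higher in submandibular gland, whereas Dcpp2 and Dcpp3 were 158-fold and 173-fold lower. The list passed without adult replicate 2 (adjusted p = 6.81e-06) or adult replicate 3 (adjusted p = 0.0311), with plain library sizes (adjusted p = 0.0134), with only the 2 groups in the fit (median 2.84, adjusted p = 0.000125), with the 50 most abundant genes removed (median 2.79, adjusted p = 0.0200), on log2(TPM + 1) with and without the filter (adjusted p = 9.43e-06 and 8.99e-05) and on log2(TPM + 0.1) (adjusted p = 1.47e-05).

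Granular duct products, mostly kallikreins and growth factors, were higher in submandibular gland in 14 of 15 members (15 adjusted over the list alone, median 3.67, adjusted p = 1.22e-19, adjusted p = 0.199 with an estimated correlation). Klk1b5 was 27.5-fold higher (9.50 ± 0.380 against 0.339 ± 0.163 CPM) and Klk1b9 12.7-fold (17.9 ± 0.513 against 1.40 ± 0.587 CPM). With 3 members at their bounds the list's median stayed 3.67. Its members summed to 367 and 122 CPM in P18 parotid, 3681 and 3490 in P18 submandibular gland and 1862 to 3298 in adult parotid. Ductal keratins and ion transport followed, with 14 of 17 members higher (16 adjusted over the list alone, median 2.63, adjusted p = 2.55e-16, adjusted p = 0.314 with an estimated correlation). In that list Foxi1, a transcription factor gene of proton-transporting cells, was 10.1-fold higher. Salivary transcription factors had 6 of 21 members higher and 1 lower (7 and 1 adjusted over the list alone, median 1.01, adjusted p = 0.000305, adjusted p = 0.377 with an estimated correlation). Pitx1 was 3.89-fold higher and Pax9 4.05-fold lower. This call ended without P18 parotid replicate 2 (median 0.55, adjusted p = 0.0529).

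Lists of the secretion machinery were also higher in submandibular gland, in samples whose cell content is open. For these lists and the duct and transcription factor lists, a difference within cells was not told apart from a different mix of tissues. In the fluid secretion list 9 of 21 members were higher and 1 lower (11 and 3 adjusted over the list alone, median 0.62, adjusted p = 0.000996, adjusted p = 0.341 with an estimated correlation). The water channel gene Aqp5 was 4.74-fold higher, while Itpr2, an intracellular calcium channel gene, was 2.23-fold lower. Regulated exocytosis had 10 of 15 members higher and 2 lower (10 and 2 adjusted over the list alone, median 1.37, adjusted p = 0.000263, adjusted p = 0.341 with an estimated correlation). The vesicle genes Syt7 and Vamp8 were 11.1-fold and 2.83-fold higher, and Sytl2 and Stx4a 9.11-fold and 1.75-fold lower. Of 25 genes of protein folding in the endoplasmic reticulum (ER), 16 were higher (21 higher and 1 lower adjusted over the list alone, median 1.03, adjusted p = 5.75e-10, adjusted p = 0.314 with an estimated correlation), with Sec23b 6.91-fold and Creld2 3.40-fold higher. The median of the fluid secretion list turned negative with plain library sizes (-0.000389) and on log2(TPM + 1) (-0.30), while camera kept ranking it above other genes. Within P18 parotid, the median genes of the fluid secretion, exocytosis, ER, ductal, transcription factor and cell cycle lists differed by -0.98, -0.22, -0.36, -1.20, -1.19 and -1.31 log2 units in replicate 2 relative to replicate 1, opposite to fat and muscle genes. The serous, granular duct and mucous medians moved the same way, by -1.85, -0.87 and -0.81.

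Among growth and development lists, 3 of 25 cell cycle genes were higher (1 adjusted over the list alone, median 0.96, adjusted p = 0.000827, adjusted p = 0.601 with an estimated correlation). The replication genes Mcm2 and Pcna were 3.71-fold and 2.24-fold higher. Branching signals went both ways, 7 of 27 higher and 3 lower (7 and 4 adjusted over the list alone, median 0.64, adjusted p = 0.0169, adjusted p = 0.339 with an estimated correlation). Ret and Wnt4 were 29.9-fold and 4.92-fold higher, and Lef1 and Fgfr1 31.1-fold and 2.05-fold lower. Myoepithelial and smooth muscle genes had 6 of 10 members higher and 1 lower (6 and 1 adjusted over the list alone, median 0.70, adjusted p = 0.0212, adjusted p = 0.314 with an estimated correlation), with the contractile genes Cnn1 and Acta2 2.81-fold and 1.93-fold higher and Des 55.3-fold lower. On log2(TPM + 1) the medians of the branching and myoepithelial lists were -0.22 and -0.12. Without P18 parotid replicate 2 the cell cycle and branching calls ended (adjusted p = 0.0666 and 0.0529), as did the branching call without adult replicate 1 (adjusted p = 0.0704), with only the 2 groups in the fit (adjusted p = 0.0634) and without both libraries that stood apart (adjusted p = 0.154).

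Lists of other cell types were lower in submandibular gland. Of 12 adipocyte genes 12 were lower (12 adjusted over the list alone, median -10.70, adjusted p = 1.50e-38, adjusted p = 0.176 with an estimated correlation, median -10.52 with 5 members at their bounds). Beside Cfd, Car3 was 1544-fold lower. In skeletal muscle 12 of 13 members were lower (13 adjusted over the list alone, median -7.33, adjusted p = 4.89e-07, adjusted p = 0.341 with an estimated correlation, median -7.29 with 1 at the bound), with the troponin gene Tnni2 and the myosin gene Myh1 123-fold and 161-fold lower. Endothelial genes were lower in 11 of 12 members (12 adjusted over the list alone, median -2.18, adjusted p = 2.56e-09, adjusted p = 0.339 with an estimated correlation), Vwf 4.11-fold and Pecam1 4.20-fold. Extracellular matrix genes were lower in 11 of 19 (13 adjusted over the list alone, median -1.26, adjusted p = 2.90e-05, adjusted p = 0.377 with an estimated correlation), with fibronectin Fn1 5.85-fold and collagen Col1a1 3.48-fold lower. These tissue genes also varied within P18 parotid. In replicate 2 the median adipocyte gene was 1.54, the median skeletal muscle gene 2.32 and the median endothelial gene 1.21 log2 units above replicate 1.

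Immune and nerve lists were lower as well. In the B and plasma cell list 9 of 11 members were lower (10 adjusted over the list alone, median -6.11, adjusted p = 9.26e-07, adjusted p = 0.341 with an estimated correlation, median -5.97 with 7 members at their bounds). The B cell receptor gene Cd79b was 65.8-fold lower and Cd79a stood at a parotid to submandibular ratio of 350 (62.8 to 13821). Of 11 T cell genes 11 were lower (11 adjusted over the list alone, median -4.44, adjusted p = 3.09e-06, adjusted p = 0.341 with an estimated correlation), Il7r 9.72-fold. Unlike fat and muscle genes, the median B cell and T cell genes differed by -2.80 and -2.43 log2 units in P18 parotid replicate 2 relative to replicate 1. Of 14 macrophage genes 8 were lower (13 adjusted over the list alone, median -1.19, adjusted p = 0.000320, adjusted p = 0.364 with an estimated correlation), Ctss 2.57-fold and Fcer1g 2.75-fold. Of 9 Schwann cell and nerve genes 4 were lower (6 adjusted over the list alone, median -1.28, adjusted p = 0.00500, adjusted p = 0.339 with an estimated correlation), with the myelin gene Mbp 2.42-fold lower. On log2(TPM + 1) the B cell, T cell and nerve calls missed the threshold with the filter (adjusted p = 0.183, 0.113 and 0.141) and without it (adjusted p = 0.173, 0.110 and 0.0662), and the nerve call also on log2(TPM + 0.1) (adjusted p = 0.120).

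Oxidative phosphorylation had 11 of 77 members lower and 2 higher (4 and 2 adjusted over the list alone, median -1.04, adjusted p = 2.76e-05, adjusted p = 0.613 with an estimated correlation). Cox8b, a subunit of muscle and brown fat, was 354-fold lower, and the muscle subunit gene Cox6a2 stood at a parotid to submandibular ratio of 403 (72.3 to 15916), while Atp5g1 and Atp5g3 were 3.27-fold and 2.11-fold higher. The list was 1.55 log2 units higher at the median in P18 parotid replicate 2 than in replicate 1, and without replicate 2 its median was -0.07 (adjusted p = 0.503). Its call also ended without both libraries that stood apart (median -0.07, adjusted p = 0.487). Cytosolic ribosomal proteins had 1 of 81 members higher and 2 lower (0 and 0 adjusted over the list alone, median 0.53, adjusted p = 9.73e-05, adjusted p = 0.613 with an estimated correlation). Rps27l was 2.21-fold higher, Rpl3l 43.0-fold lower and Rpl39l at a parotid to submandibular ratio of 34.8 (9.63 to 287). The ribosomal median was -0.08 with plain library sizes and -0.40 on log2(TPM + 1), and without the TPM filter the call ended (adjusted p = 0.552).

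The interferon list had 4 of 15 members lower (1 higher and 4 lower adjusted over the list alone, median -0.57, adjusted p = 0.110, adjusted p = 0.613 with an estimated correlation), with Zbp1 and Rsad2 11.6-fold and 2.80-fold lower. Without submandibular replicate 1 it passed (median -0.96, adjusted p = 0.00147), as it did with no filter on low counts (adjusted p = 0.0488). Of 13 immediate early and heat shock genes 0 passed, over all genes and adjusted over the list alone (median -0.52, adjusted p = 0.676, adjusted p = 0.896 with an estimated correlation), Nr4a1 having 34.9 ± 2.55 CPM in parotid and 57.4 ± 10.9 in submandibular gland. The erythroid and pancreatic lists had 1 measured member each and were not tested. Alas2, the heme synthesis enzyme of red cells, was 30.5 ± 16.1 and 8.90 ± 0.886 CPM (adjusted p = 0.227). Cela1, with 2 counts in submandibular gland, stood at a parotid to submandibular ratio of 9.99 (2.76 to 82.5), adjusted p = 0.0458, a call that leaving out any of the 7 libraries ended. Altogether 19 of 23 tested lists passed, 10 up and 9 down, and 0 with an estimated correlation.

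**Figure D2:**
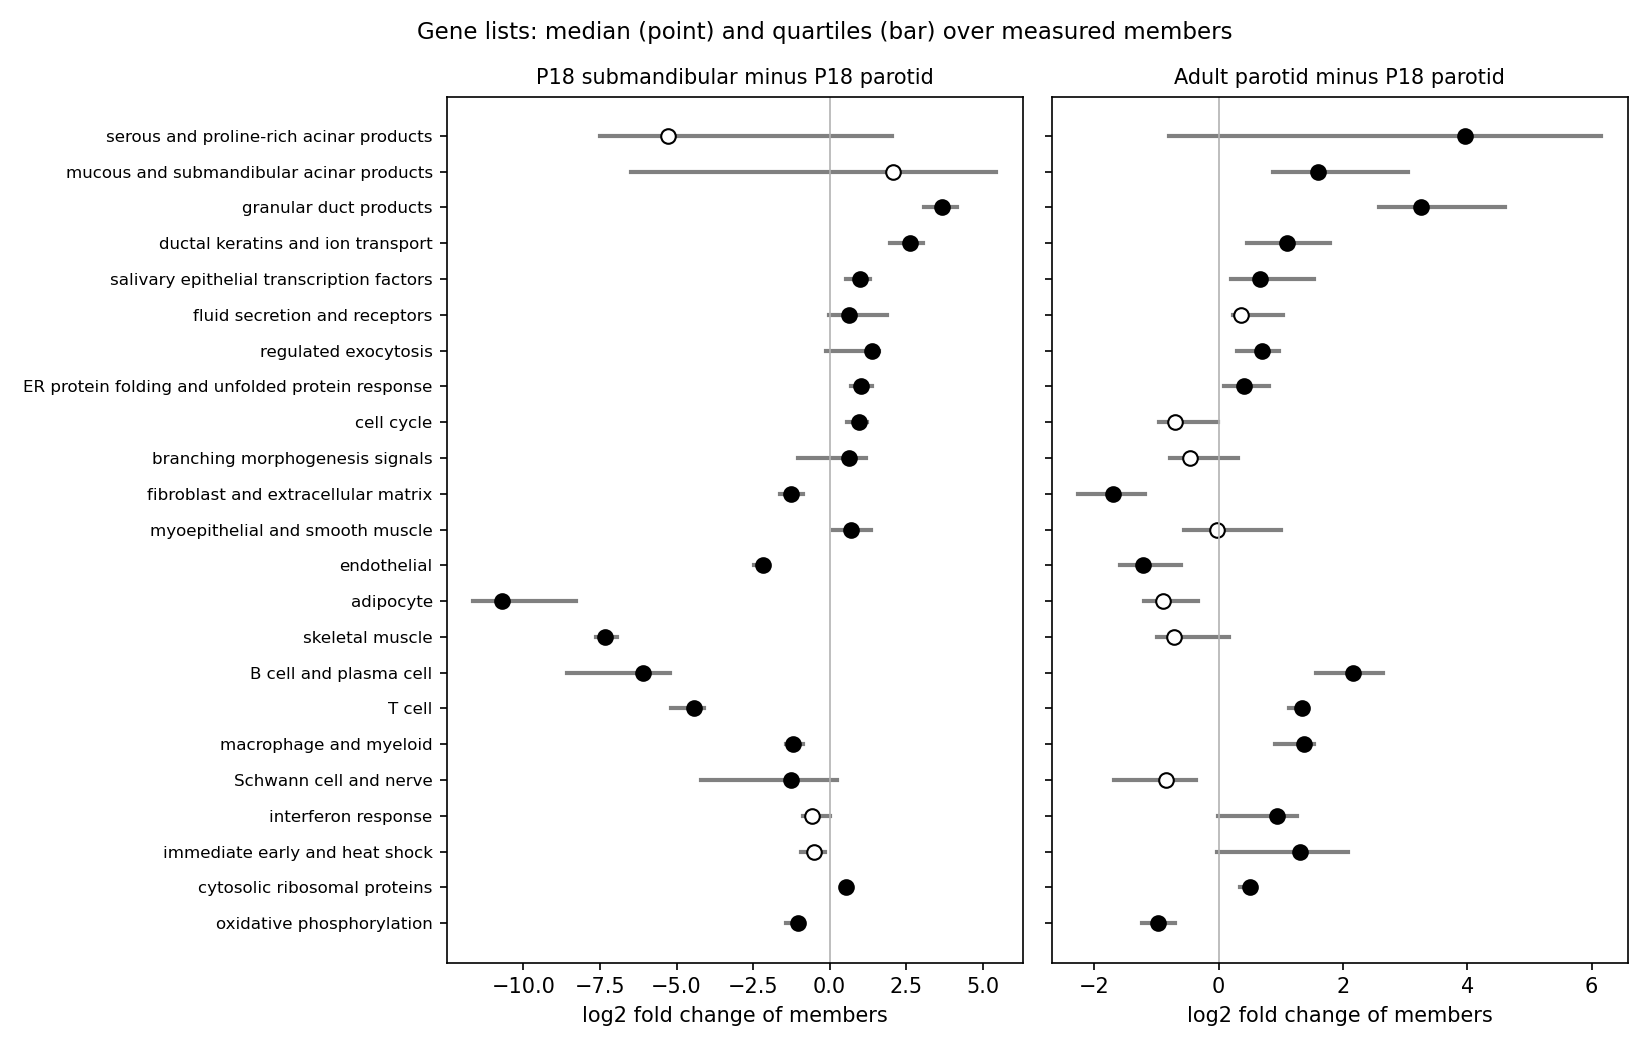
Log2 fold changes (horizontal axes) of the measured members of 23 gene lists for P18 submandibular minus P18 parotid and adult minus P18 parotid. Points are medians, bars span the quartiles, and filled points mark lists past a camera adjusted p of 0.05 at the preset correlation. Adipocyte genes had a median of -10.70 between the glands and -0.90 between the ages. With plain library sizes or log2(TPM + 1), medians of all genes move down in both panels and several positive list medians turn negative.

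P18 submandibular gland was then set against adult parotid, where gland and age differ together. Ret (4.56 ± 0.16, adjusted p = 0.000138), Agr2 (7.30 ± 0.74, adjusted p = 0.000913) and Smgc (14.58 ± 3.08, adjusted p = 0.00992) were higher here too, whereas Car6 (0.92 ± 0.77, adjusted p = 0.375) and Aqp5 (0.42 ± 0.38, adjusted p = 0.414) did not pass. Adipoq (-10.90 ± 0.84, adjusted p = 0.000432) and Cd79b (-8.37 ± 1.02, adjusted p = 0.00150) were lower in submandibular gland. This contrast called 2930 genes higher and 2997 lower. Of the gland calls at P18, 861 of 1537 increases (56.0%) and 1483 of 2149 decreases (69.0%) passed in the same direction against adult parotid, 2344 genes, and 21 and 46 in the opposite direction. Independent lists would share 298 increases and 426 decreases. The 50 simulated draws sharing the submandibular libraries without group effects shared 0.04 genes on average. Without effects few genes can be called, so that count does not measure what the shared libraries add. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.743 (0.561 in the simulation) and a covariance of 2.42 (0.130). Part of the excess may come from the shared libraries, which at n = 2 were not split. Less their part, estimated from the difference of log2 CPM between these 2 libraries, the covariance is 2.37. Log2 CPM shrink differences at low counts more than the fitted fold changes do, so that part may be understated. Without a submandibular library the count was 317 (replicate 1) or 121 (replicate 2), without adult replicate 2 it was 1382, and the whole contrast then called 2218, 2016 and 3817 genes. Plain library sizes and log2(TPM + 1) moved the median of all genes by 0.63 and 0.90 and the share of higher calls from 49.4% to 79.8% and 88.9%.

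The labels give parotid at P18 and at 12 weeks, and adult parotid was set against P18 parotid. Car6 was 18501 ± 4606 CPM in the adult against 21.0 ± 14.9 at P18 (9.78 ± 1.23, adjusted p = 0.00368), the acidic chitinase gene Chia 42059 ± 12734 against 225 ± 178 (7.55 ± 1.68, adjusted p = 0.0190) and the secreted nuclease gene Dnase1 21576 ± 915 against 116 ± 134 (7.54 ± 1.28, adjusted p = 0.00874). The collagen gene Col1a1 fell from 942 ± 62.1 to 259 ± 22.3 CPM (-1.86 ± 0.25, adjusted p = 0.00463, edgeR). Rpph1, the RNA of ribonuclease P, fell from 2696 ± 623 to 1.79 ± 1.32 CPM (-10.58 ± 0.83, adjusted p = 0.00124).

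In total 1625 genes rose and 2290 fell, 3915 of 15129, of which 290 and 780 changed by 4-fold or more. Of these calls 3913 had no overlap between the libraries of both groups, as had 54.0% of all genes, where chance gives 20%. The other rises named by size were Slpi, a protease inhibitor gene (326-fold), Wfdc12 (209-fold), the casein gene Csn3 (167-fold), the major urinary protein gene Mup5 (134-fold) and the immunoglobulin joining chain gene Igj (113-fold). Slpi had an SD above its adult mean (68.9 ± 96.0 CPM), and Igj was 160 ± 136 CPM in the adult. All 8 falls named by size were histone genes or short RNAs that lack a poly(A) tail. Rnu12, a spliceosomal RNA, and Hist1h4c, without an adult count, fell at least 999-fold and at least 414-fold. Hist2h2bb and Hist1h4d stood at P18 to adult ratios of 933 (258 to 7704) and 656 (224 to 3181), and Scarna10, a small Cajal body RNA, at 5044 (905 to 199208). Snora74a, a small nucleolar RNA, and Rmrp, the RNA of ribonuclease MRP, fell 965-fold and 833-fold. The next falls, picked after leaving those classes out, were Kng2 (31.0-fold), the imprinted H19 (26.6-fold), Zbtb20 (25.2-fold), the muscle titin gene Ttn (24.6-fold), Apold1 (22.5-fold), the nuclear RNA Malat1 (21.8-fold), the imprinted Peg3 (15.9-fold) and the transferrin receptor gene Tfrc (15.6-fold).

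Leaving out adult replicate 2 lowered the count to 1306, either submandibular library to 2150 or 2168 and adult replicate 3 to 1861, while leaving out P18 parotid replicate 1 raised it to 6073. Of 65 named genes past the threshold 38 kept their calls whichever library was left out, and Aqp5, Atp5g1, Axin2, Cd79b, Cidea, Cox7a1, Cox8b, Fgf1, Gfra3, Kcnn4, Kdr, Krt14, Krt5, Mbp, Mki67, Myh11, Myh8, Mylk, Nrtn, Oas1a, Ptch1, Retn, Rpl29, Rps21, Slpi, Tek and Zfp36 lost theirs in some. With only the 2 groups in the fit 2183 genes were called, 53 of the named ones among them, and against a fold of 2 there were 562, with 25 of the named. Without both libraries that stood apart there were 6518. Plain library sizes and log2(TPM + 1) moved the median of all genes by -1.24 and -1.67 and the share of rises from 41.5% to 1.52% of 10957 and 0.723% of 12595 calls. On log2(TPM + 1) the rises of Atp5g1, Atp5g3, Bst2, C1qb, Dnajb9, Fgf1, Gfra3, Herpud1, Kcnn4, Krt14, Krt5, Nr4a1, Retn, Rpl29, Rps21, Stx4a, Vamp8 and Xbp1 became values below 0. The same held with plain library sizes for Atp5g1, Atp5g3, Fgf1, Gfra3, Krt14, Retn, Rpl29, Rps21 and Stx4a. Further calls lost, without a turn, were those of Aqp5, Cd79b, Fcer1g, Nrtn, Oas1a, Pitx1, Scnn1a and Zfp36 on log2(TPM + 1) and of Aqp5, Bst2, C1qb, Cd79b, Dnajb9, Herpud1, Kcnn4, Krt5, Nr4a1, Nrtn, Oas1a, Pitx1, Vamp8, Xbp1 and Zfp36 with plain library sizes. The rises below are therefore relative to the median gene.

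The serous list rose with age, with 5 of 14 members up and 1 down (7 and 1 adjusted over the list alone, median 3.96, adjusted p = 0.000100, adjusted p = 0.642 with an estimated correlation). Prol1 rose 93.3-fold and Amy1 by 5.84 ± 1.69 log2 units (adjusted p = 0.0420), whereas Smr2 stood at a P18 to adult ratio of 41.0 (11.4 to 339). Bpifa2 did not pass the test (3.36 ± 1.97, adjusted p = 0.233), with 64437 and 17559 CPM at P18 and 499752, 367998 and 392505 in the adult. With the 50 most abundant genes removed the list's median was -1.82 (adjusted p = 0.445), and without both libraries that stood apart it was 2.41 (adjusted p = 0.250). Granular duct products rose in 12 of 15 members (14 adjusted over the list alone, median 3.25, adjusted p = 3.37e-18, adjusted p = 0.451 with an estimated correlation), Klk1b4 39.8-fold and Klk1b5 23.0-fold, to 6.56 ± 0.391 and 7.93 ± 1.08 CPM. Ductal keratins and ion transport had 6 of 17 members up (10 up and 1 down adjusted over the list alone, median 1.11, adjusted p = 0.000129, adjusted p = 0.642 with an estimated correlation), with the sodium channel gene Scnn1a up 6.63-fold. The ductal median turned negative with plain library sizes (-0.15) and on log2(TPM + 1) (-0.66), as did the mucous median on log2(TPM + 1) (-0.14). In the mucous list Dcpp2 alone of 10 rose, 14.6-fold, over all genes and adjusted over the list alone (median 1.60, adjusted p = 0.0494, adjusted p = 0.642 with an estimated correlation), and the call ended without P18 parotid replicate 2 (adjusted p = 0.397), without adult replicate 2 (median 0.11, adjusted p = 0.826) with the 50 most abundant genes removed (adjusted p = 0.0740), with no filter on low counts (adjusted p = 0.0786) and without both libraries that stood apart (adjusted p = 0.364).

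Of 15 exocytosis genes 6 rose (7 up and 1 down adjusted over the list alone, median 0.70, adjusted p = 0.00158, adjusted p = 0.642 with an estimated correlation), among them Vamp8 (2.39-fold) and Stx4a (1.97-fold). Of 25 ER folding genes 8 rose (8 adjusted over the list alone, median 0.41, adjusted p = 0.00382, adjusted p = 0.642 with an estimated correlation), among them Herpud1 (2.62-fold) and Dnajb9 (2.46-fold). Of 21 salivary transcription factor genes 4 rose (4 adjusted over the list alone, median 0.67, adjusted p = 0.00615, adjusted p = 0.642 with an estimated correlation), among them Xbp1 (2.90-fold), a regulator of the secretory pathway, and Pitx1 (4.01-fold). Fluid secretion did not pass (4 of 21 up and 3 down, 6 and 3 adjusted over the list alone, median 0.36, adjusted p = 0.0557, adjusted p = 0.642 with an estimated correlation), though the potassium channel gene Kcnn4 and Aqp5 rose 3.23-fold and 3.53-fold, and Itpr2 and the adrenergic receptor gene Adra1a fell 4.85-fold and 4.42-fold. These 4 medians were negative on log2(TPM + 1) (-1.13, -1.41, -0.84 and -1.22) and with plain library sizes (-0.56, -0.85, -0.59 and -0.88). The exocytosis call ended on log2(TPM + 1) with and without the filter (adjusted p = 0.0690 and 0.834) and on log2(TPM + 0.1) (adjusted p = 0.0732). The ER call ended with plain library sizes (adjusted p = 0.215) and on log2(TPM + 0.1) (adjusted p = 0.959), and on log2(TPM + 1) it ended with camera's direction turned, with and without the filter (adjusted p = 0.861 and 0.0921). The ER and transcription factor calls ended without P18 parotid replicate 2 (adjusted p = 0.0587 and 0.257) and without both libraries that stood apart (adjusted p = 0.113 and 0.0556). The fluid secretion list passed without P18 parotid replicate 1 (median 1.10, adjusted p = 0.00141), submandibular replicate 2 (adjusted p = 0.0399) or adult replicate 1 (adjusted p = 0.0382), and with no filter on low counts (adjusted p = 0.0133). Although its medians there were negative, camera also ranked it above other genes past the threshold with plain library sizes (adjusted p = 0.0187), on log2(TPM + 1) (adjusted p = 0.00560) and on log2(TPM + 0.1) (adjusted p = 0.00677).

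Cell cycle genes had 1 of 25 members down, the proliferation marker Mki67 (5.73-fold), and 0 adjusted over the list alone (median -0.71, adjusted p = 0.210, adjusted p = 0.791 with an estimated correlation). Mki67 was 282 and 77.3 CPM in the P18 parotid libraries and 58.1, 18.0 and 18.4 CPM in the adult libraries. The list passed without P18 parotid replicate 2 (median -1.21, adjusted p = 0.0124) or adult replicate 1 (median -1.49, adjusted p = 0.000637) or both (median -2.06, adjusted p = 1.03e-13), and its median was 0.20 without P18 parotid replicate 1. Branching signals had 2 of 27 members up and 3 down (2 and 3 adjusted over the list alone, median -0.47, adjusted p = 0.686, adjusted p = 0.791 with an estimated correlation), with a median of 0.07 without P18 parotid replicate 1. Nrtn and Fgf1 rose 3.93-fold and 1.70-fold, and the pathway targets Axin2 and Ptch1 fell 3.13-fold and 2.15-fold. The myoepithelial list had 2 of 10 members up and 2 down (3 and 2 adjusted over the list alone). Its median was -0.02 while its mean of 0.51 and camera pointed up (adjusted p = 0.686, adjusted p = 0.791 with an estimated correlation). The basal keratin genes Krt5 and Krt14 rose 3.27-fold and 2.18-fold, and the contractile genes Myh11 and Mylk fell 1.91-fold and 1.67-fold.

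Extracellular matrix genes fell in 15 of 19 members (16 adjusted over the list alone, median -1.70, adjusted p = 3.14e-10, adjusted p = 0.642 with an estimated correlation), Col6a3 5.16-fold and Col5a1 4.77-fold. Endothelial genes fell in 5 of 12 (8 adjusted over the list alone, median -1.21, adjusted p = 0.00484, adjusted p = 0.642 with an estimated correlation), the receptor genes Kdr and Tek 3.82-fold and 3.07-fold. Oxidative phosphorylation had 6 of 77 members down and 3 up (2 and 3 adjusted over the list alone, median -0.97, adjusted p = 0.000440, adjusted p = 0.735 with an estimated correlation), with Cox8b down 5.12-fold, Cox7a1 down (-2.46 ± 0.51) and Atp5g3 and Atp5g1 up 2.24-fold and 1.86-fold. Without P18 parotid replicate 2, whose endothelial and oxidative phosphorylation genes were higher than in replicate 1, both calls ended (medians -0.30 and 0.03, adjusted p = 0.226 and 0.442), as they did on log2(TPM + 1) (adjusted p = 0.0932 and 0.0992), on log2(TPM + 0.1) (adjusted p = 0.121 and 0.194) and without both libraries that stood apart (adjusted p = 0.113 and 0.830). Adipocyte genes did not pass as a list (1 of 12 up and 1 down, 1 and 1 adjusted over the list alone, median -0.90, adjusted p = 0.288, adjusted p = 0.791 with an estimated correlation), with Retn up 2.05-fold and Cidea down 4.34-fold. The list passed without P18 parotid replicate 1 (median -1.38, adjusted p = 0.000265), and without replicate 2 its median was 0.12. Skeletal muscle had 1 of 13 members down, Myh8 (11.8-fold), and 0 adjusted over the list alone (median -0.72, adjusted p = 0.468, adjusted p = 0.816 with an estimated correlation), and its median was 1.24 without P18 parotid replicate 2. Camera ranked it above other genes past the threshold with plain library sizes (adjusted p = 0.0250), on log2(TPM + 1) (adjusted p = 0.000819) and on log2(TPM + 0.1) (adjusted p = 0.000125), where its medians were negative as well. Schwann cell and nerve genes had 1 of 9 up and 3 down (2 and 5 adjusted over the list alone, median -0.85, adjusted p = 0.168, adjusted p = 0.642 with an estimated correlation), with Gfra3 up 2.14-fold and Ncam1 and Mbp down 3.22-fold and 1.58-fold, and passed without adult replicate 3 (adjusted p = 0.0479).

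Immune lists rose with age. Of 14 macrophage genes 9 rose (11 adjusted over the list alone, median 1.38, adjusted p = 3.13e-06, adjusted p = 0.642 with an estimated correlation), Fcer1g 3.85-fold and the complement gene C1qb 2.92-fold. Of 11 B and plasma cell genes 3 rose (6 adjusted over the list alone, median 2.16, adjusted p = 0.000338, adjusted p = 0.642 with an estimated correlation), Igj 113-fold and Cd79b 5.03-fold. Of 11 T cell genes 0 passed over all genes and 0 adjusted over the list alone, while their median of 1.33 passed camera (adjusted p = 0.0171, adjusted p = 0.656 with an estimated correlation). Lck, a T cell kinase gene, gave 1.44 ± 0.73, adjusted p = 0.176. The T cell call ended without P18 parotid replicate 2 (median 0.66, adjusted p = 0.397) or adult replicate 1 (median 0.89, adjusted p = 0.0762), in which T cell genes were 1.05 log2 units above the other adult libraries. Without both it ended with camera's direction turned (median 0.13, adjusted p = 0.966). Interferon genes rose in 5 of 15 (5 adjusted over the list alone, median 0.94, adjusted p = 0.0155, adjusted p = 0.642 with an estimated correlation), Bst2 2.55-fold and Oas1a 4.66-fold, a call that ended without P18 parotid replicate 2 (adjusted p = 0.117) and without both libraries that stood apart (adjusted p = 0.113). The macrophage and interferon calls ended on log2(TPM + 1) without the filter (adjusted p = 0.0868 and 0.251).

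Immediate early and heat shock genes rose in 4 of 13 (6 adjusted over the list alone, median 1.32, adjusted p = 0.0194, adjusted p = 0.656 with an estimated correlation), Nr4a1 2.69-fold and Zfp36 4.15-fold, and the call ended without P18 parotid replicate 1 or adult replicate 2 (adjusted p = 0.249 and 0.0528). The immediate early and heat shock list summed to 267, 811 and 352 CPM in adult replicates 1, 2 and 3, and to 191 and 282 CPM in P18 parotid. On log2(TPM + 1) the medians of the macrophage, T cell, interferon and immediate early lists were -0.53, -0.29, -0.84 and -0.62. With plain library sizes the interferon median was -0.31. Cytosolic ribosomal proteins had 4 of 81 members up and 0 adjusted over the list alone (median 0.51, adjusted p = 0.000189, adjusted p = 0.709 with an estimated correlation), among them Rps21 (1.89-fold) and Rpl29 (1.67-fold), with medians of -0.75 with plain library sizes and -1.41 on log2(TPM + 1). The ribosomal call ended on log2(TPM + 1) and log2(TPM + 0.1) with camera's direction turned (adjusted p = 0.308 and 0.742), and on log2(TPM + 1) without the filter camera ranked the list below other genes past the threshold (adjusted p = 0.00209). With a gene length trend as an offset, chosen after seeing the data, the ribosomal call ended (median 0.21, adjusted p = 0.0548), as it did without both libraries that stood apart (median 0.24, adjusted p = 0.113). The length offset also ended the mucous call (median 1.30, adjusted p = 0.0737), and the fluid secretion list passed with it (median 0.67, adjusted p = 0.00515). Alas2 and Cela1, the measured members of the erythroid and pancreatic lists, gave -0.69 ± 0.85 and 0.01 ± 0.60 (adjusted p = 0.566 and 0.992). Altogether 16 of 23 tested lists passed, 13 up and 3 down, 0 with an estimated correlation, 10 without P18 parotid replicate 2 and 8 without both libraries that stood apart.

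**Figure D3:**
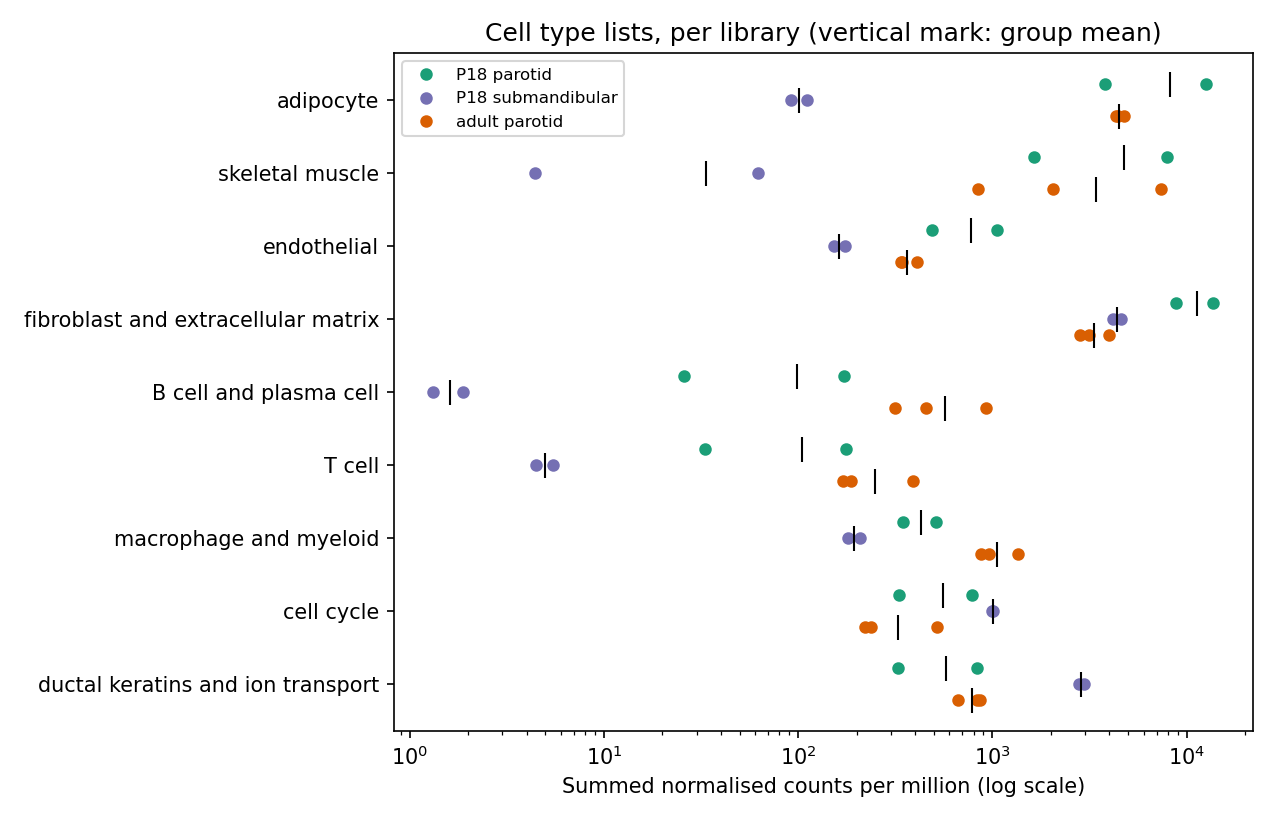
Summed normalised CPM (horizontal axis, log scale) of the members of 9 cell type lists in each library. Points are libraries and vertical marks group means (n = 2, 2 and 3). Adipocyte genes summed to 3819 and 12543 CPM in P18 parotid, 91.7 and 111 in P18 submandibular gland and 4320 to 4733 in adult parotid.

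RNA classes that lack a poly(A) tail, grouped after the falls with age were seen, were low in all adult libraries. Of 56 replication-dependent histone genes 48 fell and 1 rose (median -5.14), and of 65 small non-coding RNA genes, such as Rnu12, Rmrp and Snora74a, 47 fell and 1 rose (median -2.77). Histone variant genes with polyadenylated mRNA and host genes of small nucleolar RNAs had medians of 0.39 and 0.49. Between the glands at P18 the medians of the histone and small RNA classes were 1.00 and 0.12. Gene length also moved with age: across genes the Spearman rho of length and fold change was -0.285 for age and -0.0221 for gland. With a gene length trend as an offset, chosen after seeing the data, 52 of 65 named age genes kept their calls, all but Aqp5, Atp5g1, Cd79b, Gfra3, Krt14, Mbp, Mki67, Myh11, Mylk, Ncam1, Retn, Rpl29 and Rps21, and 70 of 71 named gland genes, all but Itpr2. Among the longest 10% of genes 681 fell and 13 rose with age.

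**Figure D4:**
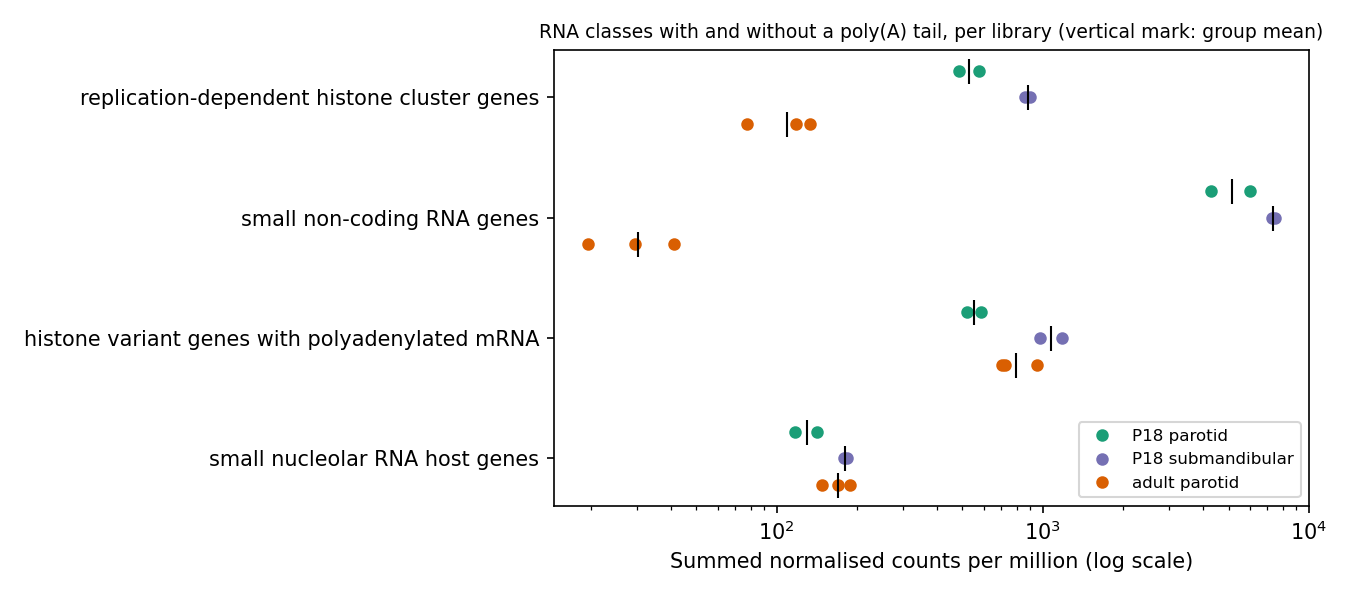
Summed normalised CPM (horizontal axis, log scale) of 4 RNA classes in each library. Points are libraries and vertical marks group means (n = 2, 2 and 3). Small non-coding RNA genes summed to 4308 and 6021 CPM in P18 parotid and 19.6 to 41.1 CPM in adult parotid.

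The gland and age comparisons share the P18 parotid libraries. Both called 1263 genes, 498 higher in both, 498 lower in both, 86 higher in submandibular gland and lower in the adult, and 181 the reverse. Car6, Prol1, Klk1b5, Pitx1, Aqp5 and Vamp8 were higher in both than in P18 parotid, and Itpr2, Mbp, Cidea and Cox8b lower in both. Independent lists would share 165, 325, 233 and 231 genes in these 4 classes. Simulated draws without group effects shared 0.02 genes on average, a count kept low by construction because few genes can be called in them. Across genes the Pearson r was 0.160 against 0.532 in the simulation, and the covariance 0.354 against 0.120. A split would leave 1 shared library to each comparison and was not made, so part of the excess may come from these libraries. Their part of the covariance, estimated from the difference between them, is 0.204, leaving 0.150. That difference was taken from log2 CPM, which shrink differences at low counts more than the fitted fold changes do. The shared part may therefore be understated and the rest overstated. Leaving out P18 parotid replicate 1 raised the count to 3176, and leaving out submandibular replicate 1 or 2 or adult replicate 2 or 3 lowered it to 144, 57, 326 or 504.

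Sex is not given in the labels. Adult parotid replicate 1 had 272 CPM of Xist, the RNA of the inactive X chromosome, and no count of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together, which at 3 counts allows up to 0.294 CPM. The other 6 libraries had 0.191 to 0.953 CPM of Xist and 2707 to 6000 Y-linked counts. These transcripts therefore differed within the adult group as they do between female and male samples. They argue against the same animal as the source of adult replicate 1 and the other adult libraries. Whether the remaining replicates came from separate animals stays open. Cell cycle genes in adult replicate 1 were 1.43 log2 units above the other adult libraries at the median.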

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

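All alternatives were planned except leaving out both libraries that stood apart, removing RNA classes without a tail, the length offset and the added falls, which were chosen after seeing the data. Over all alternatives, gene values kept their direction and side of the threshold 2740 times, lost the call 418 times, gained it 12 times, moved without a call 15 times and turned 67 times. List results kept theirs 806 times, lost the call 51 times, gained it 26 times, moved 24 times and turned 13 times. Counts stayed within 1.5 times 96 times and moved further 54 times. DESeq2 size factors, upper quartile factors, removal of the 50 most abundant genes, no filter on low counts, DESeq2, the length offset and removal of RNAs without a tail kept all counts of genes within 1.5 times; DESeq2 gave 4450 gland and 4841 age calls, with more false calls than edgeR in the simulation. For the changes below the cause was not tested, except that a fold minimum lowers a count by construction. Leaving out libraries lowered some counts and raised others. Depth limits genes with few counts, for which only bounds and wide intervals were given.

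Counts are given in the order gland, age, submandibular against adult, both gland and age, and standing against both ages. Plain library sizes gave 5967 gland, 10957 age and 4448 shared calls. Log2(TPM + 1) gave 9291, 12595, 9022, 8422 and 1359, without the filter 9941, 14170, 8977, 8879 and 1338, and log2(TPM + 0.1) gave 8689, 12546, 9593 and 7764 for the first 4. A test against a fold of 2 gave 969, 562, 2093, 81 and 595, and the fits of 2 groups 1349 gland and 2183 age calls. Without both libraries that stood apart there were 6245, 6518, 9345, 2899 and 4259, and 8 age lists passed. Leaving out 1 library gave 148 to 5397, 1306 to 6073, 2016 to 7824, 57 to 3176 and 121 to 3273, with 16 to 20 gland lists and 10 to 17 age lists. With replicate number as a block there were 1496 age and 433 shared calls, and the other counts stayed within 1.5 times. Of 71 named gland genes 65 kept their calls with the block, all but Cela1, Fgfr1, Itpr2, Pax9, Smgc and Stx4a. Of 65 named age genes 40 did, all but Aqp5, Atp5g1, Chia, Cidea, Cox7a1, Cox8b, Fgf1, Gfra3, Kcnn4, Kdr, Krt14, Krt5, Mbp, Mki67, Mylk, Nrtn, Oas1a, Pitx1, Ptch1, Retn, Rpl29, Rps21, Stx4a, Tek and Xbp1. The block ended the gland calls of the myoepithelial list (median 0.70, adjusted p = 0.126) and the branching list (median 0.65, adjusted p = 0.0554), and the skeletal muscle list passed for age (median -1.18, adjusted p = 0.00407). Whether the numbers pair the samples is open. Across genes, deviations from the group mean correlated at 0.239 between P18 parotid and P18 submandibular libraries of the same number, and at -0.239 otherwise. With 2 libraries in a group these values are opposite by construction and cannot decide it. Same-number values were 0.0844 and 0.0104 between P18 and adult parotid, and -0.0171 and -0.0174 between P18 submandibular gland and adult parotid. No list passed with an estimated correlation, for gland (0) or age (0). From TPM the 10 most abundant genes held 25.2%, 59.8% and 77.6% in P18 parotid, P18 submandibular and adult parotid.

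Values that turned concern age unless stated. With plain library sizes they were Stx4a -0.26, Fgf1 -0.46, Krt14 -0.13, Retn -0.21, Gfra3 -0.15, Rps21 -0.34, Rpl29 -0.51, Atp5g3 -0.0684 and Atp5g1 -0.36. On log2(TPM + 1), with and without the filter, they were Xbp1 -0.34, Kcnn4 -0.11, Vamp8 -0.65, Stx4a -0.90, Dnajb9 -0.59, Herpud1 -0.50, Fgf1 -1.01, Krt5 -0.0729, Krt14 -0.68, Retn -0.87, C1qb -0.32, Gfra3 -0.59, Cela1 -0.94, Bst2 -0.54, Nr4a1 -0.50, Rps21 -1.001, Rpl29 -1.16, Atp5g3 -0.74 and Atp5g1 -1.002. On log2(TPM + 0.1) they were Xbp1 -0.34, Kcnn4 -0.11, Vamp8 -0.65, Stx4a -0.93, Dnajb9 -0.60, Herpud1 -0.50, Fgf1 -1.11, Krt5 -0.0677, Krt14 -0.71, Retn -0.90, C1qb -0.33, Gfra3 -0.77, Cela1 -1.78, Bst2 -0.55, Nr4a1 -0.52, Zfp36 -0.00107, Rps21 -1.002, Rpl29 -1.16, Atp5g3 -0.74 and Atp5g1 -1.01. For lists, a turn is one of camera's direction against other genes, and the values are medians. The skeletal muscle list had -1.87 with plain library sizes, -2.39 on log2(TPM + 1) and -2.42 on log2(TPM + 0.1). The ribosomal list had -1.41, without the filter -1.41, and -1.44 on log2(TPM + 0.1), and the ER list -1.41 on log2(TPM + 1) with and without the filter (-1.41). The serous list had -5.68 and -6.15 for gland on log2(TPM + 1) and log2(TPM + 0.1), and -1.82 for age without the 50 most abundant genes. The oxidative phosphorylation list had 0.0301 without P18 parotid replicate 2, and the T cell list 0.13 without both libraries that stood apart. Without P18 parotid replicate 1 the oxidative phosphorylation median was -1.50 and had not turned.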

Other observations

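All tests of explanations in this part were chosen after the results were seen. The 2 P18 parotid libraries differed from each other in genes that also separated the glands, some in the same direction and some against it. Fabp4, a fatty acid carrier of fat and vessels, was 1057 CPM in replicate 1 and 3927 in replicate 2, and the skeletal actin gene Acta1 186 and 1259. The proliferation gene Top2a was 111 and 36.9, the T cell gene Lck 26.3 and 3.99, and the B cell gene Cd79b 21.8 and 5.15. Of the genes called higher in P18 parotid than in submandibular gland, 68.1% were higher in replicate 2 than in replicate 1, against 23.4% of those called higher in submandibular gland and 48.5% of genes not called. Of the genes called higher in P18 parotid, 714 were over 2-fold higher in replicate 2. Against that direction, 308 were over 2-fold lower in it, among them 9 B cell, 11 T cell and 5 serous genes. Lck and Cd79b thus ran opposite to the gland difference. In the first 2 principal components of all libraries (59.0% and 25.2% of the variance) the P18 parotid libraries lay at 58.1 and 109 on the second.

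Several genes that differed between the glands at P18 or between the ages did not pass between P18 submandibular gland and adult parotid. They include the collagen gene Col1a1 (0.06 ± 0.25, adjusted p = 0.863) and the vascular receptor gene Kdr (-0.21 ± 0.37, adjusted p = 0.685), picked from the genes named above, and a p that misses the threshold does not show equal levels. Prol1 (5.97 ± 0.62, adjusted p = 0.00101) and Sec23b (2.07 ± 0.24, adjusted p = 0.00132) were higher in submandibular gland against either age. Muc19, which shares exons with Smgc, gave 5.38 ± 3.67, adjusted p = 0.324 (edgeR) between the glands at P18. Its CPM were 0.272 and 0 in P18 parotid, 8.05 and 3.74 in P18 submandibular gland, and 0, 218 and 0.0483 in adult parotid. Among adult libraries, Smgc (0, 24.1 and 0.0483 CPM) and Lman1l (0.0979, 24.9 and 0.0965 CPM) were also high in replicate 2 alone. The adult libraries share the fit, so this spread adds to the errors of these genes between the glands. Its source was not tested.

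The first pattern is the low level of RNAs without a poly(A) tail in adult parotid. The median of small non-coding RNA genes lay -3.26 log2 units from that of the polyadenylated host genes of small nucleolar RNAs. This class was grouped after some of its members were seen among the largest falls, so the value restates those falls and leaves open whether the libraries kept such RNAs to different extents. If fewer dividing cells were the whole cause of the histone fall, and both sets followed dividing cells alike, cell cycle genes should fall as far. Their median was 4.43 log2 units above that of the histone genes. It was 0.20 without P18 parotid replicate 1 and -2.06 without both libraries that stood apart, against -5.14 for the histone genes in all libraries. These values argue against it as the whole cause only under that assumption, which was not tested. Small non-coding RNA genes summed to 4308 to 7451 CPM in the P18 libraries of both glands and to 19.6 to 41.1 CPM in adult parotid. A difference in preparation between the ages would go with age and could not be told apart from it. This holds for these RNAs and for all other age calls, and a true fall with age is not excluded.

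The second pattern is the higher level of fat, muscle, vessel and lymphoid genes in P18 parotid than in P18 submandibular gland. Tissue taken up with the gland in dissection would vary between libraries, and the median adipocyte gene differed by 1.54 log2 units between the P18 parotid libraries, which cannot tell uptake from a true difference of the glands. The median T cell gene differed by -2.43 log2 units, opposite to the adipocyte genes. This is 1 pair of libraries, and tissue taken up can differ in lymphoid content, so uptake as the source of the lymphoid genes stays open. A true gland difference was not excluded for any of these lists.

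The third pattern is the rise of lymphoid lists with age. The B cell list's median was 1.67 without adult replicate 1, where it passed camera at the preset correlation. Its rise therefore did not rest on that library alone. Without P18 parotid replicate 2 its median was 1.45, but 1 P18 parotid library was left, so that library's part stays open. The T cell list's median was 0.89 without adult replicate 1, which cannot tell. Without P18 parotid replicate 2 it was 0.66 and did not pass. T cell genes had been seen to be low in that library, so leaving it out had to lower the rise, and 1 P18 parotid library was left, so the source of the T cell call stays open.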
